A study of Homo sapiens with 12 samples.

How the data were processed

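RNA from L-540, an established line of Hodgkin lymphoma cells, was measured on Illumina bead arrays in 12 samples, 3 in each of 4 groups: control, 100 nM givinostat, 5 µM sorafenib, and both drugs together, called the combination here. Givinostat is a histone deacetylase inhibitor and sorafenib a multikinase inhibitor, and exposure lasted 24 hours per the labels. The labels letter the samples of each group A, B and C and do not say whether these were separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

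Per the labels' protocols, the authors extracted total RNA with Trizol and column clean-up and labelled it as biotinylated cRNA, and the labels name BeadStudio, without a version, as the processing tool. The deposited table of raw values holds 1 average bead intensity per probe and array on the linear scale, with no normalization between arrays and no background subtracted. A second deposited column per array is a fraction between 0 and 1 that the file header calls a detection p-value. It rose with intensity on all 12 arrays, so it was read as 1 minus the detection p. The deposited series matrix holds the same intensity values after quantile normalization across the 12 arrays, still on the linear scale; its method is not named in the sources used here, and it was read from the 12 columns, whose values at equal rank differ by at most 0.276%.

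The raw intensity values were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the negative-control mean and spread from the detection p-values, with an offset of 16, and gives log2 values. A probe was kept when its detection p was under 0.05 on all 3 arrays of at least 1 group, which left 11801 probes. Gene symbols came from the platform annotation given with the data: 28098 probes had 1 symbol, 13 had several and 20692 had none listed there. The Entrez identifiers of 28059 probes matched the human RefSeq gene table (assembly GRCh38), which was used for names only and updated 0 symbols; the platform annotation can be old. Of the kept probes, 10052 had 1 symbol, and the brightest probe per gene by its mean over the 12 arrays gave 8079 genes. Neither chromosome positions nor isoforms are given, because the values belong to probes.

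Each gene was fitted with limma's lmFit and eBayes over all 12 arrays, with 1 coefficient per group and 8 residual degrees of freedom, so that all groups share an estimate of the spread. There were 6 comparisons: each drug against control, the combination against control, against givinostat and against sorafenib, and the interaction (combination minus givinostat minus sorafenib plus control, on the log2 scale). A gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05. The log2 changes carry limma's standard error (SE), each from 3 arrays per group, and adjusted p-values are limma's throughout. Fold changes are 2 to the power of the log2 change. Where a gene's tested probe was detected on none of the 3 arrays of the lower group, the fold is given as a lower bound against the intensity at the detection limit of those arrays ("at least"). Where it was detected on 1 or 2 of the 3, the number is said, and a printed fold has the undetected arrays at that limit; the log2 change, SE and adjusted p remain those of the measured values.

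The design, the 30 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The replicate block without the combination arrays and the list tests without combination B or in that block were added after. The rule names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 3 values in a group all lie above or all below the 3 of the other group, which chance alone gives for 10% of genes. It adds, for each list, up to 4 members past the threshold with the largest change, and, whatever their values, BCL2L11, CDKN1A, MCL1, RIPK1, RIPK3, MLKL, HDAC1, HDAC2, DUSP6, ATF4, DDIT3, TXNIP and MYC; a further gene of the rule is not reported here. Lists with at least 3 measured members, 26 of the 30, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with the correlation estimated from the data. The lists of B cell markers and of endothelial markers had 1 measured member each, and those of fibroblast and epithelial markers had none, so these 4 were not tested. Counts of list members are given over all 8079 genes and adjusted over the list alone.

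The letters were checked for pairing by correlating, across genes, each array's deviations from its group mean with those of the same letter in another group. Between control, givinostat and sorafenib all 9 same-letter correlations lay between 0.177 and 0.408. In these 3 groups the letters were therefore treated as pairing the samples, from this check and not from the labels. For each drug against control, gene counts with the letter as a replicate block are given beside the main ones, with list values where stated. The SE and adjusted p of each named gene, and the counts of list members, come from the fit without the block. Whether the response of each drug held in the presence of the other was compared by the correlation of log2 changes across genes between comparisons that share no array. For the overlap of both single-drug responses, which share the control arrays, 100 draws of unchanged groups against those controls were simulated, with independent arrays and, after the results were seen, with arrays of the same letter correlated at 0.32, the mean of the 9 values.

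The tests were tried on simulated data for all 5 pairwise comparisons, with 100 genes changed by 1 log2 unit and 100 by 2. The noise was independent and normal with each gene's residual variance, so correlation between genes or by letter was absent. From 6 to 14 unchanged genes passed per comparison. Of the genes changed by 1 unit, 67% were recovered for givinostat against control, 63% for sorafenib against control, 53% for the combination against control, 66% for the combination against givinostat and 64% for the combination against sorafenib. The Benjamini-Hochberg adjustment is stricter where fewer genes change than were planted. Recovery may therefore be lower in comparisons with few calls, as for givinostat against control (7 genes) and the combination against sorafenib (29). Alternatives covered background correction, normalization, the detection filter, probes per gene, the variance model, the arrays in the fit, the replicate letter, the set-test correlation and the leaving out of each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The in vivo treatment named in the series title is not analysed here, since all 12 samples were treated in vitro. For arrays, the number of arrays and the signal over background limit the precision.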

Results

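Gene expression was measured on 12 bead arrays of L-540 cells, 3 each for control, givinostat, sorafenib and the combination. The median raw intensity lay between 418.1 and 579.3 on 11 arrays and was 681.1 on combination B. Between 24.6% and 30.9% of the probes were detected on those 11 arrays, against 22.4% on combination B. After normalization, the correlation across genes was 0.965 to 0.983 between arrays of the same group (12 pairs) and 0.951 to 0.979 between arrays of different groups (54 pairs); genes are not independent replicates. The standard deviation of an array's deviations from its group mean was 0.329 for combination B and 0.305 for combination A on the log2 scale, and 0.237 to 0.277 for the other 10 arrays. Values after a gene are log2 changes ± SE with n = 3 arrays per group, followed by the fold and limma's adjusted p.

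**Figure D1:**
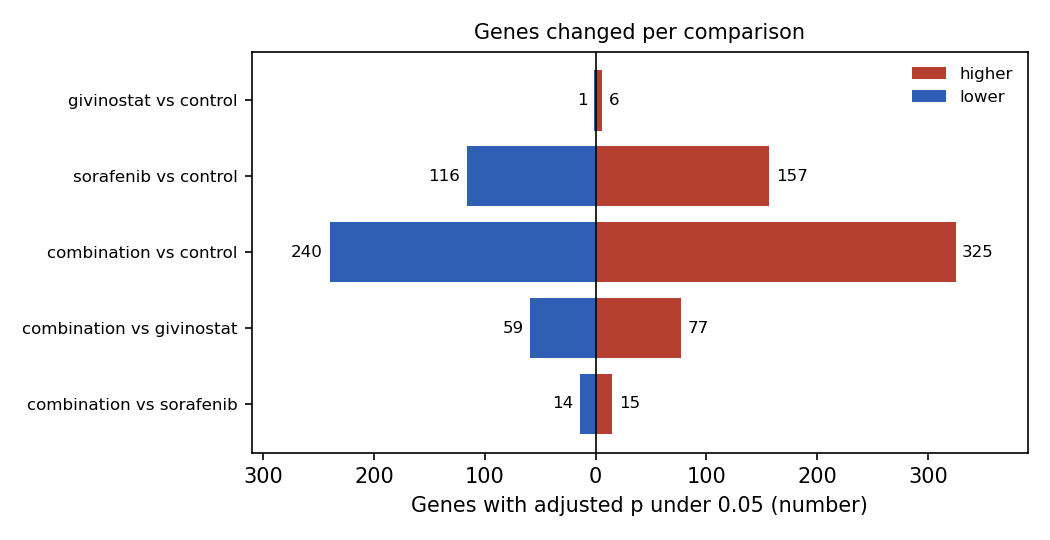
Number of genes with a limma adjusted p under 0.05 in each pairwise comparison (horizontal axis, number of genes), higher to the right and lower to the left. The combination against control had 325 higher and 240 lower genes, and givinostat against control had 6 higher and 1 lower.

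Givinostat alone was compared with control to find the response to the histone deacetylase inhibitor. ANKRD29, detected on 1 of the 3 control arrays, rose by 1.90 ± 0.21 (2.96-fold, adjusted p = 0.0133) and RAPH1, an adaptor of lamellipodia, by 1.5 ± 0.22 (2.83-fold, adjusted p = 0.0466). STAT4, a transcription factor of interleukin-12 signalling, rose by 1.26 ± 0.17 (2.39-fold), the integrin beta-1 gene ITGB1 by 0.85 ± 0.13 (1.80-fold) and IRAG2 by 0.80 ± 0.12 (1.74-fold), each with an adjusted p of 0.0466. ANKRD22, whose tested probe was detected on none of the control arrays, was at least 2.11-fold higher (adjusted p = 0.0466). DNLZ, an escort protein of mitochondrial HSP70, fell by 1.13 ± 0.17 (2.19-fold lower, adjusted p = 0.0466).

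By gene group, the NF-kB target list shifted down in the givinostat arrays, with 14 of 15 measured members negative and a median log2 change of -0.72 (camera adjusted p = 0.000407, and adjusted p = 0.657 with an estimated correlation). Over all genes none of the 15 passed limma's test, 3 were lower at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. The member with the lowest value, the cytokine gene LTA, chosen after its values were seen, had a log2 change of -2.25. Interferon-stimulated genes also shifted down, with 17 of 20 members negative and a median of -0.26 (adjusted p = 0.00238, and adjusted p = 0.646 with an estimated correlation). None of the 20 passed over all genes, 6 were lower at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. The ATF4 stress response list (median -0.24, 23 of 30 negative) shifted down with an adjusted p of 0.00506, and adjusted p = 0.657 with an estimated correlation. The JAK-STAT target list (median -0.30, 12 of 16 negative) shifted down with an adjusted p of 0.0231, and adjusted p = 0.733 with an estimated correlation. In the ATF4 list 4 members and in the JAK-STAT list 2 were lower at an unadjusted p under 0.05, and in both no member passed limma's test over all genes or adjusted over the list alone. The list of G2/M and mitosis genes shifted up (median 0.14, 29 of 38 positive, adjusted p = 0.0479, and adjusted p = 0.646 with an estimated correlation). None of its members passed over all genes, 3 were higher at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone. The ATF4 list no longer passed without control A (adjusted p = 0.22), givinostat B (0.121) or givinostat C (0.135), and the JAK-STAT list without control A (0.58), givinostat B (0.178) or givinostat C (0.135). The G2/M list no longer passed without control B (0.0836), control C (0.203), givinostat A (0.356), givinostat B (0.0517), combination A (0.0649) or combination C (0.0507). It was also lost with array median scaling (0.0602) and with a detection p under 0.01 on all 12 arrays (0.0974). With the letter as a replicate block, camera's adjusted p was 1.76e-07 for NF-kB targets and 0.0418 for G2/M genes. It was 0.00105 for each of the interferon, ATF4 and JAK-STAT lists, all at the preset correlation. Without the combination arrays the block gave 5.16e-08, 0.0415, 0.00166, 0.0026 and 0.00257 in that order. The fits without 1 array and with an estimated correlation did not use the letter.

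With limma, 7 of 8079 genes changed with givinostat, 6 higher and 1 lower, and 5 of them by at least 2-fold; 1042 had an unadjusted p under 0.05. With the letter as a replicate block the count was 166 (103 higher and 63 lower), including all 7, and with the block and the combination arrays left out it was 146 (88 and 58), again with all 7. The count moved to 1 without control A, B or C, sorafenib A, sorafenib C or combination C, to 3 without sorafenib B, combination A or combination B, to 0 without givinostat B or C, and to 21 without givinostat A. The split was 48 higher and 28 lower both without background correction and in the series matrix values, and 22 and 8 with a background model fitted to the intensities alone. Of the genes always named, givinostat gave changes that did not pass for CDKN1A (0.05 ± 0.20, adjusted p = 0.95), MCL1 (-0.14 ± 0.31, adjusted p = 0.9), HDAC1 (0.10 ± 0.13, adjusted p = 0.808), HDAC2 (-0.02 ± 0.27, adjusted p = 0.986) and MYC (0.17 ± 0.14, adjusted p = 0.69). BCL2L11 was detected on none of the 12 arrays by any of its probes, DUSP6 and TXNIP were each detected on at most 1 array, and no probe is named for RIPK1.

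Sorafenib alone was compared with control to find the response to the kinase inhibitor. TRIB3, a pseudokinase induced by ATF4, rose by 2.00 ± 0.26 (4.00-fold, adjusted p = 0.00416), and CCPG1, a receptor for autophagy of the endoplasmic reticulum, by 1.78 ± 0.23 (3.44-fold, adjusted p = 0.00416). ITGAL, the alpha chain of the leukocyte integrin LFA-1, was below background on the control arrays and at least 2.86-fold higher (adjusted p = 0.000431). HK2, the hexokinase at the entry of glycolysis, fell by 1.66 ± 0.21 (3.16-fold lower, adjusted p = 0.00377), and the cytokine gene IL22 fell by 2.09 ± 0.24 (4.26-fold lower, adjusted p = 0.00323). The linker histone gene H1-2 fell by 1.79 ± 0.25 (3.47-fold lower, adjusted p = 0.00488).

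The other largest rises with sorafenib were CSNK1G1, a casein kinase gene (2.07 ± 0.21), ALOX5AP, needed for leukotriene synthesis (1.91 ± 0.17), the phosphatase gene CDC14B (1.86 ± 0.13), SH3RF2 (1.71 ± 0.32), TNFSF14, which encodes the cytokine LIGHT (1.57 ± 0.35), the lysosomal sulfatase gene ARSG (1.54 ± 0.25) and RIPOR2 (1.47 ± 0.21). The other largest falls were HLX, a homeobox gene (-1.64 ± 0.34), the protein kinase C gene PRKCH (-1.54 ± 0.26), the transporter gene SLCO4A1 (-1.41 ± 0.28), ANKRD37 (-1.40 ± 0.31), the phosphodiesterase gene PDE1B (-1.38 ± 0.22) and ZNF395 (-1.38 ± 0.19). H2AC8, a core histone gene, was below background on the sorafenib arrays and at least 1.68-fold lower. PDE1B was detected on 2 of the 3 sorafenib arrays. These 14 genes had limma adjusted p-values from 0.000195 for CDC14B to 0.0463 for H2AC8.

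By gene group, hypoxia and glycolysis genes fell with sorafenib: 10 of 21 measured members fell and 11 did not pass, and 13 fell when adjusted over the list alone (median -0.69, camera adjusted p = 1.07e-11, and adjusted p = 0.00161 with an estimated correlation). Besides HK2 and ANKRD37 they included EGLN1, an oxygen-sensing hydroxylase (-1.10 ± 0.22, detected on 2 of the 3 sorafenib arrays), and the glycolytic kinase PGK1 (-1.07 ± 0.14). Of 15 heat shock chaperones, 3 fell and 12 did not pass, with 8 falls adjusted over the list alone (median -0.40, adjusted p = 1.82e-05, and adjusted p = 0.0145 with an estimated correlation). They were the HSP90 co-chaperones STIP1 (-0.90 ± 0.12) and FKBP4 (-0.78 ± 0.17) and the HSP40 gene DNAJB1 (-0.60 ± 0.15). Of 18 antigen presentation genes, 2 rose and 16 did not pass, both over all genes and adjusted over the list alone (median 0.30, adjusted p = 0.00059, and adjusted p = 0.0334 with an estimated correlation). These were the MHC class II gene HLA-DMB (0.76 ± 0.15) and CD74, which encodes the invariant chain of MHC class II (0.67 ± 0.15).

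The ATF4 stress response list shifted up with sorafenib: 4 of 30 members rose and 26 did not pass, and 16 rose when adjusted over the list alone (median 0.58, adjusted p = 4.06e-09, and adjusted p = 0.171 with an estimated correlation). Besides TRIB3 they were PPP1R15A, the stress-induced phosphatase subunit GADD34 (1.02 ± 0.22), the transcription factor CEBPB (0.76 ± 0.18) and the glycyl-tRNA synthetase GARS1 (0.68 ± 0.15). DDIT3, the transcription factor CHOP, had a log2 change of 1.19 ± 0.32 that did not pass (adjusted p = 0.0696), and ATF4 itself one of 0.56 ± 0.21 (adjusted p = 0.177). CDK inhibitors and p53 targets shifted up (median 0.52, adjusted p = 0.000149, and adjusted p = 0.157 with an estimated correlation). None of the 12 members passed limma's test over all genes, 6 were higher at an unadjusted p under 0.05, and 6 rose when adjusted over the list alone.

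The cholesterol biosynthesis list shifted down with sorafenib, with all 15 members negative: 2 fell and 13 did not pass, and 6 fell when adjusted over the list alone (median -0.60, adjusted p = 2.75e-06, and adjusted p = 0.0604 with an estimated correlation). The members that fell were INSIG1, a sterol sensor (-1.23 ± 0.20), and the reductase DHCR7 (-0.88 ± 0.19). Of 35 DNA replication genes, 4 fell and 31 did not pass, with 6 falls adjusted over the list alone (median -0.27, adjusted p = 7.25e-06, and adjusted p = 0.218 with an estimated correlation). They were the ribonucleotide reductase subunit RRM2 (-0.995 ± 0.20), the flap endonuclease FEN1 (-0.95 ± 0.21), the licensing factor CDT1 (-0.83 ± 0.15) and the helicase subunit MCM4 (-0.78 ± 0.16). Of 38 G2/M genes, CCNA2, which encodes cyclin A2, fell (-0.49 ± 0.12) and 37 did not pass, with 3 falls adjusted over the list alone (median -0.26, adjusted p = 2.65e-05, and adjusted p = 0.107 with an estimated correlation). In the histone and HDAC inhibitor marker list, H1-2 fell and 5 members did not pass, with 4 falls adjusted over the list alone (median -0.84, adjusted p = 0.000149, and adjusted p = 0.171 with an estimated correlation). Of 16 JAK-STAT targets, the feedback inhibitor CISH (-0.99 ± 0.24) and the kinases PIM1 (-0.98 ± 0.21) and PIM2 (-0.78 ± 0.16) fell and 13 did not pass, with 5 falls adjusted over the list alone. That list had a median of -0.47 (adjusted p = 0.000609, adjusted p = 0.445 with an estimated correlation, and 0.068 without control A).

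Ribosome biogenesis genes shifted down with sorafenib, with a median of -0.27 (adjusted p = 0.00625, adjusted p = 0.445 with an estimated correlation, and 0.0657 without sorafenib A). None of the 22 passed limma's test over all genes, 6 were lower at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.08 (adjusted p = 0.0262, and adjusted p = 0.107 with an estimated correlation), and the call was lost without control A (0.0523) or sorafenib A (0.0901), with cyclic loess (0.0566) and in the replicate block without the combination arrays (0.0545). None of the 31 passed limma's test over all genes or adjusted over the list alone, and 6 were lower and 1 higher at an unadjusted p under 0.05. Endoplasmic reticulum (ER) chaperones had a median of -0.33 (adjusted p = 0.0322, and adjusted p = 0.119 with an estimated correlation); SYVN1, an ER ubiquitin ligase, rose (0.75 ± 0.16), the secreted ER factor MANF fell (-0.68 ± 0.11), and 15 did not pass, with the same counts adjusted over the list alone. This call was lost in the replicate block (0.068), in the block without the combination arrays (0.0719), with a detection p under 0.01 on all 12 arrays (0.0758), and without control A (0.059), control B, sorafenib B or sorafenib C (0.0521 each). In lists that did not shift, TNFRSF8, which encodes the Hodgkin marker CD30, fell (-0.98 ± 0.20, adjusted p = 0.0316), the mitophagy receptor BNIP3L fell (-1.31 ± 0.31, adjusted p = 0.049), and the autophagy gene ATG12 rose (0.53 ± 0.12, adjusted p = 0.0436).

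With limma, 273 of 8079 genes changed with sorafenib, 157 higher and 116 lower, and 79 of them by at least 2-fold. With the letter as a replicate block the count was 706 (394 higher and 312 lower), including all 273, and with the combination arrays left out of the block it was 714 (396 and 318), including 265. The count fell to 125, 85 and 70 without control A, B and C, to 120, 98 and 71 without sorafenib A, B and C, to 166 and 179 without givinostat B and C, and to 142 without combination C. With array median scaling the split was 11 higher and 13 lower. The genes always named that did not pass included CDKN1A (0.41 ± 0.20, adjusted p = 0.297), MCL1 (-0.08 ± 0.31, adjusted p = 0.917), RIPK3 (-0.48 ± 0.26, adjusted p = 0.333) and MLKL (-0.11 ± 0.33, adjusted p = 0.891).

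**Figure D2:**
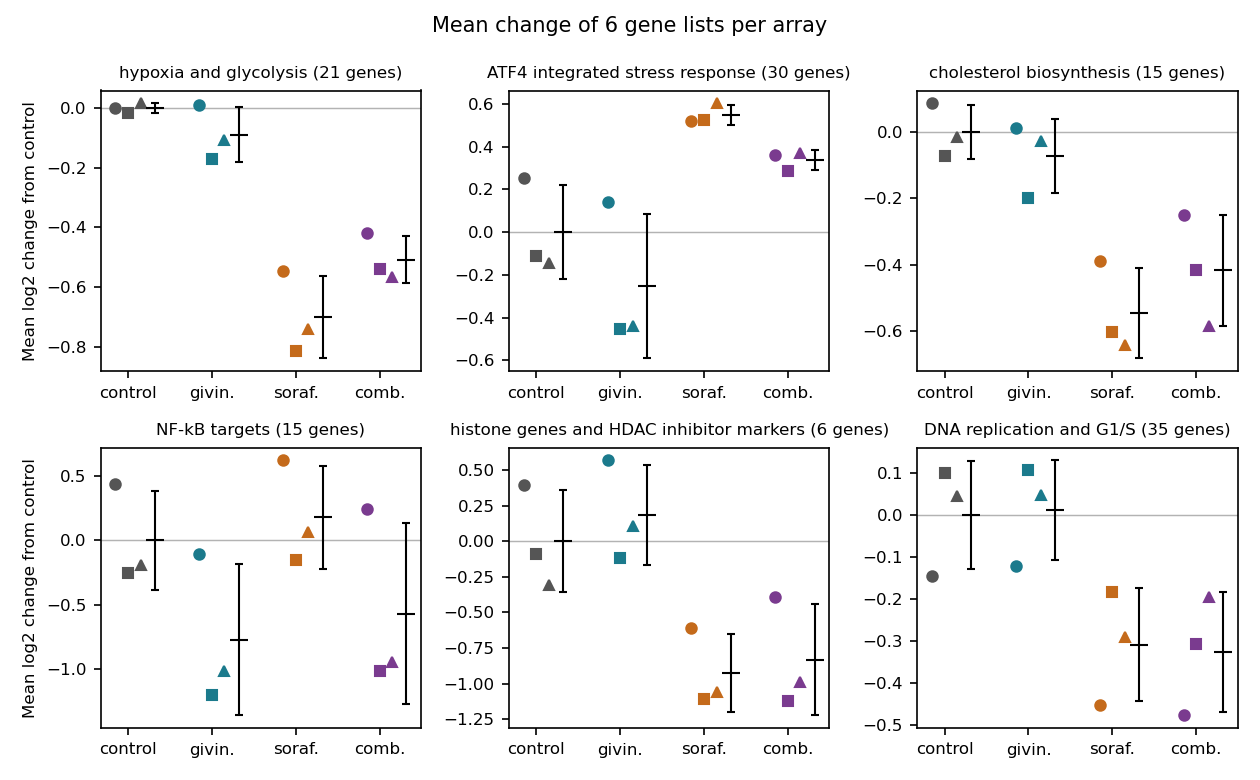
Mean log2 change from the control mean (vertical axis) of the measured members of 6 fixed gene lists on each array, by group (horizontal axis); circles, squares and triangles are letters A, B and C, and bars give the mean ± SD of 3 arrays. The hypoxia and glycolysis list lay at -0.813 to -0.547 on the sorafenib arrays and at -0.566 to -0.419 on the combination arrays.

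The combination was compared with control to find the response to both drugs together. MTAP, an enzyme of methionine salvage, was below background on the control arrays and at least 8.64-fold higher in the combination (adjusted p = 0.000847), and COBLL1 was likewise at least 6.76-fold higher (adjusted p = 0.00313). TNFRSF21, which encodes death receptor 6, rose by 2.57 ± 0.31 (5.92-fold, adjusted p = 0.00198). The cytokine gene LTA fell by 2.42 ± 0.42 (5.36-fold lower, adjusted p = 0.00943). PRKCH was below background on the combination arrays and at least 3.58-fold lower (adjusted p = 0.00118).

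The other largest rises were the matrix gene TNC (at least 3.12-fold), LOC101927822 (2.47 ± 0.32), SH3RF2 (2.21 ± 0.32), LINC01727 (2.20 ± 0.19), ANKRD22 (at least 2.38-fold), the delta-globin gene HBD (2.11 ± 0.44) and ANKRD29 (2.09 ± 0.21). The other largest falls were PRKAR1B, a regulatory subunit of protein kinase A (-2.31 ± 0.45), the surface glycoprotein gene CD200 (-2.18 ± 0.45), the olfactory receptor gene OR3A1 (at least 2.65-fold lower), NCKIPSD (-2.04 ± 0.27), the calcium-binding protein gene S100P (at least 2.65-fold lower), the mRNA export factor gene ALYREF (-1.78 ± 0.41), the transcription factor gene ATF5 (-1.65 ± 0.34) and the glycogen branching enzyme gene GBE1 (-1.61 ± 0.24). Of these, LOC101927822, HBD and ANKRD29 were detected on 1 of the 3 control arrays, and PRKAR1B, CD200, NCKIPSD, ALYREF and GBE1 on 1 of the 3 combination arrays. These changes rest partly on background signal. Their limma adjusted p-values lay between 0.000847 for LINC01727 and 0.0271 for ALYREF.

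**Figure D3:**
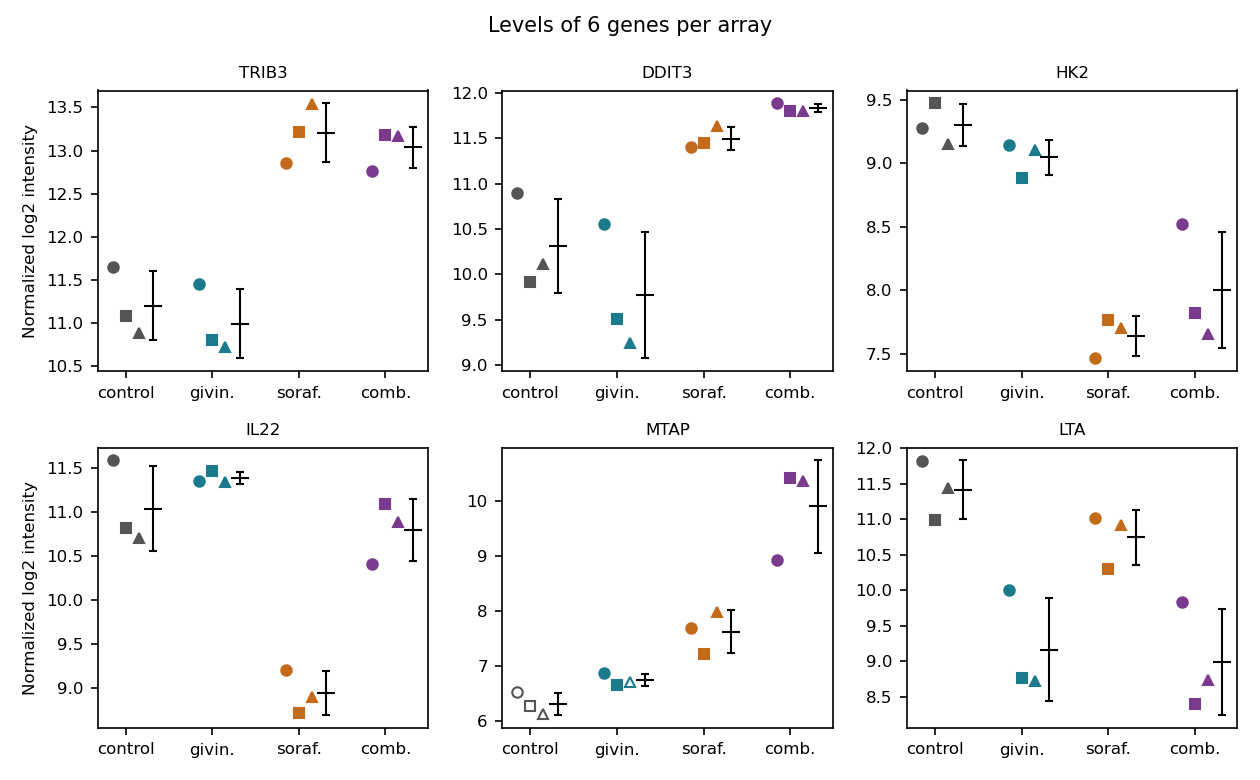
Normalized log2 intensity (vertical axis) of 6 genes on each array, by group (horizontal axis); circles, squares and triangles are letters A, B and C, open symbols mark arrays on which the probe was not detected, and bars give the mean ± SD of 3 arrays. The mean of IL22 was 11.04 in control, 11.39 with givinostat, 8.94 with sorafenib and 10.79 with the combination.

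By gene group, hypoxia and glycolysis genes fell with the combination: 6 of 21 fell and 15 did not pass, with 10 falls adjusted over the list alone (median -0.39, adjusted p = 1.01e-05, and adjusted p = 0.0183 with an estimated correlation). They included ANKRD37 (-1.31 ± 0.31), HK2 (-1.30 ± 0.21), TPI1 (-0.85 ± 0.11) and PGK1 (-0.84 ± 0.14). Of 15 heat shock chaperones, 6 fell and 9 did not pass, with 8 falls adjusted over the list alone (median -0.48, adjusted p = 6.70e-05, and adjusted p = 0.0192 with an estimated correlation). They included the collagen chaperone SERPINH1 (-1.19 ± 0.19, detected on 2 of the 3 combination arrays), STIP1 (-0.80 ± 0.12), HSPA8 (-0.78 ± 0.13) and HSPH1 (-0.74 ± 0.15). The ATF4 list shifted up: 6 of 30 members rose, ATF5 fell and 23 did not pass, with 11 rises and 2 falls adjusted over the list alone (median 0.36, adjusted p = 0.000205, and adjusted p = 0.357 with an estimated correlation). The members that rose included TRIB3 (1.83 ± 0.26), DDIT3 (1.52 ± 0.32, adjusted p = 0.0208) and the transsulfuration enzyme CTH (0.99 ± 0.26).

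All 22 ribosome biogenesis genes were negative in the combination: 4 fell and 18 did not pass, with 9 falls adjusted over the list alone (median -0.39, adjusted p = 2.67e-05, and adjusted p = 0.299 with an estimated correlation). These were NOLC1 (-0.87 ± 0.19), POLR1C (-0.76 ± 0.19), BYSL (-0.62 ± 0.14) and LYAR (-0.59 ± 0.15). Of 35 DNA replication genes, 4 fell and 31 did not pass, both over all genes and adjusted over the list alone (median -0.33, adjusted p = 6.70e-05, and adjusted p = 0.317 with an estimated correlation). These were the uracil glycosylase UNG (-1.25 ± 0.27), UHRF1 (-0.89 ± 0.20), POLE (-0.56 ± 0.15) and ORC1 (-0.53 ± 0.14). Of 16 JAK-STAT targets, CISH (-1.51 ± 0.24), the cytokine OSM (-0.98 ± 0.18), IL2RA (-0.92 ± 0.19) and BATF (-0.74 ± 0.20) fell and 12 did not pass, with 5 falls adjusted over the list alone. That list had a median of -0.46 (adjusted p = 9.17e-05, and adjusted p = 0.357 with an estimated correlation). Of 15 cholesterol biosynthesis genes, INSIG1 (-1.10 ± 0.20), FDPS (-0.83 ± 0.20), EBP (-0.70 ± 0.16) and DHCR7 (-0.70 ± 0.19) fell and 11 did not pass, with 6 falls adjusted over the list alone. That list had a median of -0.48 (adjusted p = 0.00213, and adjusted p = 0.27 with an estimated correlation).

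In the histone and HDAC inhibitor marker list, H1-2 fell with the combination (-1.01 ± 0.25) and 5 did not pass, with 5 falls adjusted over the list alone (median -0.86, adjusted p = 0.00213, and adjusted p = 0.299 with an estimated correlation). Of 20 interferon-stimulated genes, SAMD9 fell (-0.57 ± 0.13) and 19 did not pass, with 5 falls adjusted over the list alone (median -0.30, adjusted p = 0.00613, adjusted p = 0.327 with an estimated correlation, and 0.0584 without control A). The G2/M list had a median of -0.20 (adjusted p = 0.00808, and adjusted p = 0.299 with an estimated correlation). None of its 38 members passed limma's test over all genes or adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05. CDK inhibitors and p53 targets had a median of 0.32 (adjusted p = 0.0483, and adjusted p = 0.361 with an estimated correlation). None of the 12 passed over all genes or adjusted over the list alone, 3 were higher at an unadjusted p under 0.05, and the call was lost without control B (0.0575), control C (0.107), givinostat C (0.0514), sorafenib B (0.0511) or combination A (0.258), and with no detection filter (0.269). In lists that did not shift, ETV5, a transcription factor downstream of ERK, rose (1.62 ± 0.29, detected on 1 of the 3 control arrays), FOSL1 was at least 1.96-fold lower, HSPA5, the main ER chaperone, fell (-1.58 ± 0.37, detected on 2 of the 3 combination arrays), PRDX1 fell (-0.63 ± 0.16), the metallothionein MT2A rose (0.97 ± 0.18) and the interleukin-7 receptor gene IL7R rose (0.80 ± 0.21). All 11 list shifts of this comparison also passed without combination B, the array with the highest background.

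With limma, 565 of 8079 genes changed with the combination, 325 higher and 240 lower, and 163 of them by at least 2-fold. The count fell to 363, 199 and 217 without control A, B and C and to 371, 248 and 285 without combination A, B and C. With array median scaling the split was 28 higher and 68 lower; that scaling moved the median change of all genes to -0.29, against -0.02 here. The genes always named that did not pass included CDKN1A (0.51 ± 0.20, adjusted p = 0.157), MCL1 (-0.68 ± 0.31, adjusted p = 0.213), RIPK3 (0.02 ± 0.26, adjusted p = 0.972), MLKL (-0.24 ± 0.33, adjusted p = 0.708), HDAC1 (-0.21 ± 0.13, adjusted p = 0.361), ATF4 (0.34 ± 0.21, adjusted p = 0.357) and MYC (-0.05 ± 0.14, adjusted p = 0.866).

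The combination was compared with givinostat to find what sorafenib added. MTAP, detected on 2 of the 3 givinostat arrays, rose by 3.16 ± 0.34 (8.41-fold, adjusted p = 0.00275). DDIT3, the stress transcription factor CHOP, rose by 2.06 ± 0.32 (4.17-fold, adjusted p = 0.0136) and TRIB3 by 2.04 ± 0.26 (4.12-fold, adjusted p = 0.00551). H3C3, a core histone gene, was below background on the combination arrays and at least 2.40-fold lower (adjusted p = 0.0127), and the linker histone gene H1-2 fell by 1.60 ± 0.25 (3.04-fold lower, adjusted p = 0.0136).

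The other largest rises were LINC01727 (1.84 ± 0.19), the GTPase regulator gene ADAP1 (1.81 ± 0.20), CCPG1 (1.68 ± 0.23), ALOX5AP (1.66 ± 0.17), CSNK1G1 (1.5 ± 0.21), SH3RF2 (1.46 ± 0.32) and the phosphatase gene PPM1M (1.44 ± 0.18). The other largest falls were SEC62, of the ER translocon (-1.43 ± 0.24), NCKIPSD (-1.37 ± 0.27), RASL11B (-1.37 ± 0.17), CISH (-1.33 ± 0.24), FASTKD2 (-1.31 ± 0.29), SBNO2 (at least 1.79-fold lower), the prothymosin gene PTMA (at least 1.66-fold lower) and the core histone gene H2AC17 (-1.26 ± 0.28). Of these, SEC62, NCKIPSD and H2AC17 were detected on 1 and FASTKD2 on 2 of the 3 combination arrays, so their changes rest partly on background signal. Their limma adjusted p-values lay between 0.0027 for LINC01727 and 0.0483 for H2AC17.

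By gene group, hypoxia and glycolysis genes fell when sorafenib was added: HK2 (-1.05 ± 0.21), PGK1 (-0.88 ± 0.14) and TPI1 (-0.72 ± 0.11) fell and 18 of 21 did not pass, with 8 falls adjusted over the list alone. That list had a median of -0.43 (adjusted p = 8.94e-06, and adjusted p = 0.0186 with an estimated correlation). Of 17 ER chaperones, PDIA4 (-1.06 ± 0.23, detected on 1 of the 3 combination arrays), HSP90B1 (-0.92 ± 0.17), CALR (-0.78 ± 0.16) and MANF (-0.58 ± 0.11) fell and 13 did not pass, with 7 falls adjusted over the list alone (median -0.35, adjusted p = 5.21e-05, and adjusted p = 0.0186 with an estimated correlation). Of 15 heat shock chaperones, HSPA8 (-0.71 ± 0.13) and STIP1 (-0.58 ± 0.12) fell and 13 did not pass, with 8 falls and 1 rise adjusted over the list alone (median -0.37, adjusted p = 0.000298, and adjusted p = 0.0268 with an estimated correlation). The ATF4 list shifted up: 5 of 30 members rose and 25 did not pass, with 17 rises and 1 fall adjusted over the list alone (median 0.62, adjusted p = 5.11e-10, and adjusted p = 0.247 with an estimated correlation). Besides DDIT3 and TRIB3 they included PPP1R15A (1.31 ± 0.22) and the tryptophanyl-tRNA synthetase WARS1 (1.22 ± 0.24).

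Of 38 G2/M genes, CCNA2 fell when sorafenib was added (-0.64 ± 0.12) and 37 did not pass, with 6 falls adjusted over the list alone (median -0.35, adjusted p = 1.24e-06, and adjusted p = 0.0756 with an estimated correlation). Of 35 DNA replication genes, RRM2 fell (-0.98 ± 0.20) and 34 did not pass, with 5 falls adjusted over the list alone (median -0.32, adjusted p = 9.33e-06, and adjusted p = 0.309 with an estimated correlation). In the histone and HDAC inhibitor marker list, H1-2 and H2BC5 (-1.16 ± 0.19) fell and 4 did not pass, with 4 falls adjusted over the list alone (median -1.06, adjusted p = 8.34e-05, and adjusted p = 0.247 with an estimated correlation). All 22 ribosome biogenesis genes were negative (median -0.31, adjusted p = 0.000298, and adjusted p = 0.322 with an estimated correlation). None of the 22 passed limma's test over all genes or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. Of 15 cholesterol biosynthesis genes, INSIG1 fell (-1.18 ± 0.20) and 14 did not pass, with 2 falls adjusted over the list alone (median -0.29, adjusted p = 0.0105, and adjusted p = 0.289 with an estimated correlation). The cholesterol call was lost without givinostat A (0.0535) or combination C (0.142). Of 16 JAK-STAT targets, CISH fell and 15 did not pass, with 3 falls adjusted over the list alone (median -0.18, adjusted p = 0.0295, and adjusted p = 0.503 with an estimated correlation). The JAK-STAT call was lost without givinostat A (0.333), combination B (0.112) or combination C (0.126), and the other 9 list shifts also passed without combination B.

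With limma, 136 of 8079 genes changed when sorafenib was added to givinostat, 77 higher and 59 lower, and 56 of them by at least 2-fold. The count fell to 14 and 61 without givinostat B and C and to 55, 62 and 48 without combination A, B and C. With array median scaling the split was 6 higher and 48 lower, and the median of all genes moved to -0.39. The genes always named that did not pass included CDKN1A (0.45 ± 0.20, adjusted p = 0.246), MCL1 (-0.54 ± 0.31, adjusted p = 0.363), RIPK3 (0.44 ± 0.26, adjusted p = 0.36) and ATF4 (0.53 ± 0.21, adjusted p = 0.2).

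The combination was compared with sorafenib to find what givinostat added. COBLL1 rose by 3.06 ± 0.53 (6.28-fold, adjusted p = 0.0391), MTAP by 2.28 ± 0.34 (4.85-fold, adjusted p = 0.0271) and ETV5, the transcription factor downstream of ERK, by 2.02 ± 0.29 (2.96-fold, adjusted p = 0.0233). COBLL1 and ETV5 were each detected on 1 of the 3 sorafenib arrays, so their changes rest partly on background signal. IL22 rose by 1.85 ± 0.24 (3.6-fold, adjusted p = 0.014). ATF5 fell by 1.94 ± 0.34 (3.84-fold lower, adjusted p = 0.0397), and the integrin gene ITGAL, detected on 2 of the 3 combination arrays, fell by 1.36 ± 0.18 (2.31-fold lower, adjusted p = 0.014).

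The other largest rises were ANKRD22 (at least 2.37-fold), RAPH1 (1.82 ± 0.22), ATP2B1-AS1 (1.51 ± 0.19), the semaphorin gene SEMA6A (1.42 ± 0.19), ELAPOR2 (1.26 ± 0.22) and the hedgehog receptor gene PTCH1 (1.04 ± 0.18). The other largest falls were S100P (at least 2.42-fold lower), the phosphatase gene PTPN7 (-1.35 ± 0.22), ZNF696 (-1.31 ± 0.22), CPLANE2 (at least 1.71-fold lower), TMEM63A (at least 1.70-fold lower), C8orf82 (-1.19 ± 0.19), SERPINH1 (-1.12 ± 0.19) and SBNO2 (at least 1.55-fold lower). ZNF696 and SERPINH1 were detected on 2 of the 3 combination arrays. Their limma adjusted p-values lay between 0.014 for RAPH1 and 0.0449 for TMEM63A. By gene group, NF-kB targets shifted down when givinostat was added, with 14 of 15 members negative (median -0.63, adjusted p = 0.00176, and adjusted p = 0.808 with an estimated correlation). None of the 15 passed limma's test over all genes, 5 were lower at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. The call was lost without sorafenib A (0.109) or combination C (0.05), and held without combination B (0.022).

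With limma, 29 of 8079 genes changed when givinostat was added to sorafenib, 15 higher and 14 lower, and 23 of them by at least 2-fold; 1259 had an unadjusted p under 0.05. The count moved to 10, 14 and 16 without control A, B and C, to 13 without givinostat C, to 0, 8 and 0 without sorafenib A, B and C, and to 0 without combination B. With array median scaling the split was 5 higher and 9 lower, and the median of all genes moved to -0.32. The genes always named that did not pass included CDKN1A (0.10 ± 0.20, adjusted p = 0.866), RIPK3 (0.50 ± 0.26, adjusted p = 0.373), DDIT3 (0.34 ± 0.32, adjusted p = 0.662) and MYC (0.02 ± 0.14, adjusted p = 0.96).

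The interaction asked where the combination departed from the sum of both single-drug effects. The hypoxia and glycolysis list shifted up in the interaction: its median was -0.69 for sorafenib alone, -0.43 for sorafenib added to givinostat and 0.26 for the difference, with 15 of 21 members positive (adjusted p = 0.00701, and adjusted p = 0.132 with an estimated correlation). None of the 21 members passed limma's test over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The call was lost with no detection filter (adjusted p = 0.149) and with detection required on all 12 arrays (0.0698), and held without combination B (0.016). Over all genes limma gave 0 with an interaction past the threshold, 473 at an unadjusted p under 0.05, and a smallest adjusted p of 0.623. RIPK3, a kinase of necroptosis, had an interaction of 0.92 ± 0.36 (adjusted p = 0.782) and DDIT3 one of 0.88 ± 0.45 (adjusted p = 0.847).

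The response to each drug was also compared in the absence and the presence of the other, between comparisons that share no array. The sorafenib changes alone and on top of givinostat had a correlation across genes of 0.528, where genes are not independent replicates. The sign was the same in 68.7% of all 8079 genes. That share was 55.2% with array median scaling, where the correlation was 0.53, and 57.4% with no detection filter. Of the 273 genes changed by sorafenib alone, such as TRIB3 and HK2, 265 had the same sign in the presence of givinostat and 66 also passed there. Of the 136 genes changed by adding sorafenib, 134 had the same sign with sorafenib alone. The givinostat changes alone and on top of sorafenib had a correlation across genes of 0.408. Here the sign was the same in 62.6% of all genes. That share was 45% with array median scaling, where the correlation was 0.397, and 55.2% with no detection filter. The same-sign share over all genes therefore depends on the normalization. All 7 genes changed by givinostat alone had the same sign in the presence of sorafenib and 3 of them passed there, and all 29 genes changed by adding givinostat had the same sign with givinostat alone.

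Givinostat alone and sorafenib alone, which share the control arrays, changed 3 genes in common, all higher with both drugs: ANKRD29 (1.90 and 0.97), IRAG2 (0.80 and 1.24) and STAT4 (1.26 and 1.17). Independent lists of these sizes would share 0.237 genes, 0.131 of them in the same direction, and unchanged groups simulated against the same controls shared 0. No gene passes in such groups, so this value says nothing about the overlap. The count moved to 6 without givinostat A, to 1 without combination A or combination C, and to 0 without control A, B or C, givinostat B or C, or sorafenib A or C. The overlap was not counted with the letter as a replicate block. The correlation of both responses across genes was 0.212, against 0.5 for simulated unchanged groups, and their covariance was 0.0268 against 0.0295 with independent arrays and 0.02 with arrays of the same letter correlated. The observed covariance lies between these, so whether both drugs share an effect across genes stays open. The same-sign share was 56.4% against 66.7% in the simulation. The 3 control arrays cannot be split into parts of 2 arrays each, so part of the overlap may come from the shared controls.

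The lists of pro-apoptotic BCL2 family genes, anti-apoptotic genes, necroptosis and death receptors, NRF2 targets, ERK pathway feedback targets, histone deacetylases, Hodgkin cell markers, autophagy and lysosome, and metallothioneins shifted in none of the 6 comparisons. The markers of T cells and of macrophages shifted in none either. Some of these lists had few measured members. These were 4 of 13 pro-apoptotic, 6 of 12 anti-apoptotic, 8 of 20 ERK pathway and 8 of 15 histone deacetylase genes. Metallothioneins had 3 of 9 and T cell markers 5 of 15. A list without a shift can hold members that moved in opposite directions. Adjusted over the list alone, the ERK list had 2 rises and 1 fall with givinostat, and 2 and 2 in the combination against control. The lowest camera adjusted p among these 11 lists was 0.087, for the 3 measured macrophage markers in the combination against control, where 1 had an unadjusted p under 0.05. No list that shifted and no named gene that passed had the opposite direction under any alternative run for it.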

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

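Both tests of the hypoxia and glycolysis pattern were chosen only after that result was seen, and the cholesterol list was added to the signal range test after the ATF4 slope was known; the test of combination B was written before its result was seen.

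The hypoxia and glycolysis list shifted in the interaction, which tests whether its response to sorafenib differed between cells without and with givinostat. Camera's adjusted p was 0.00701 at the preset correlation and 0.132 with an estimated correlation. Of its 21 members, 1 had an unadjusted p under 0.05. In the random draws of the arrays given below, 82 of 100 reached at least 1 shifted list. Chance is therefore not excluded for this difference, although drug effects can remain in the drawn groups. Combination B as the sole source is argued against, since the list still passed without it (adjusted p = 0.016, and 0.00159 to 0.149 over all alternatives). The slope of the list's sorafenib response with givinostat against that without was 0.589 (95% bootstrap interval 0.493 to 0.683). The slope intervals resample list members and not arrays, so they do not measure the spread between arrays. A narrower signal range on the combination arrays stays open, because the ATF4 list had a slope of 1.05 (0.86 to 1.27), which argues against a narrowing alike for all genes, and the cholesterol list one of 0.683 (0.3 to 0.97), which does not. Over the 273 genes changed by sorafenib alone the slope was 0.643, inside the interval of the hypoxia and glycolysis list. Those genes were picked by their change with sorafenib alone, which can itself lower a slope. Whether the response is specific to glycolysis genes or a general shrinkage of sorafenib changes therefore stays open. The pattern was also found and tested on the same arrays.

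Combination B stood apart from the other 11 arrays in raw median intensity (681.1 against 418.1 to 579.3) and in detected probes (22.4% against 24.6% to 30.9%). If its higher background shrank fold changes, its sorafenib response should be smaller than that of combination A and C. The slope ratio over 50 genes was 0.977 (95% bootstrap interval 0.899 to 1.05), above the bound of 0.8 set beforehand. The interval resamples genes and not arrays, so it does not measure the spread between arrays. Combination B correlated best with the arrays lettered C and combination C with those lettered B. An exchange of both letters could give that pattern, but it was not tested further; without combination B the count for the combination against control was 248. No biological explanation was tested.

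Probes with no gene listed, which the comparisons by gene do not use, also changed: 37 of 1749 in sorafenib against control (2.12%, and 2.32% of named probes), 69 in the combination against control (3.95%, and 5.2% of named probes), 21 in the combination against givinostat (1.20% and 1.31%) and 9 in the combination against sorafenib (0.515% and 0.348%).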

How the results depend on the processing

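The replicate block without the combination arrays and the list tests without combination B or in that block were chosen after seeing the data; all other alternatives were planned. No list shift, named gene that passed or transfer correlation changed sign. Counts are genes changed, in the order givinostat, sorafenib and the combination against control, then the combination against givinostat and against sorafenib (main: 7, 273, 565, 136 and 29); a count within 1.5 times the main one is left out unless given for order. The interaction gave 0 in every alternative run for it, which leaves out fits on only the compared groups and the block without the combination arrays.

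Without background correction the counts were 76, 487, 808, 362 and 99, and in the series matrix values 76, 479, 807, 364 and 99. With a background model fitted to the intensities alone they were 30, 331, 702, 213 and 47. With cyclic loess the givinostat count was 18. With array median scaling the counts were 14, 24, 96, 54 and 14, and the median change of all genes moved to 0.09, 0.03, -0.29, -0.39 and -0.32, and to -0.42 for the interaction. That scaling also turned the majority direction of the genes changed: for sorafenib from 157 higher and 116 lower to 11 and 13, for the combination against control from 325 and 240 to 28 and 68, against givinostat from 77 and 59 to 6 and 48, and against sorafenib from 15 and 14 to 5 and 9. The near-even split against sorafenib also turned with the mean of probes (14 and 15), probes tested singly (16 and 19), and without givinostat A (14 and 16) or combination C (8 and 13). With no detection filter the counts were 1, 65, 177, 33 and 8, where 18852 genes were tested, and with a detection p under 0.01 on all 12 arrays 24, 397, 672, 267 and 45. The mean of a gene's probes gave 2 for givinostat and probes tested singly gave 1. A variance trend with robust eBayes gave 75, 434, 795, 346 and 74. Fits on only the compared groups, which have fewer residual degrees of freedom, gave 0, 35, 144, 5 and 0. For the other changes of count the cause was not tested.

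With the letter as a replicate block the counts were 166, 706, 1068, 590 and 175, and without the combination arrays 146 and 714; the block kept 559 of the 565 genes of the combination against control and all 136 and 29 of the others. Same-letter correlations with the combination lay between -0.139 and 0.363, and 10 of 12 arrays correlated best with their own letter, a hint from the data and not the design. Among the 41 list shifts, the block on all 12 arrays ended only that of ER chaperones with sorafenib (0.068), and it added 4: NF-kB targets in the combination against control (0.0592 to 0.00594), CDK inhibitors and p53 targets against givinostat (0.0684 to 0.0142), and against sorafenib hypoxia and glycolysis (0.064 to 0.0395) and ribosome biogenesis (0.064 to 0.027). Without the combination arrays the block also ended the shift of oxidative phosphorylation with sorafenib (0.0545). Of 205 results for a named gene in a comparison, passing or not, the block on all 12 arrays left 203 the same. The other 2 passed only with the block. Without the combination arrays the block left 68 of 70 the same, with 1 call lost and 1 gained.

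Leaving out 1 array gave 0 to 21 genes for givinostat, 70 to 260 for sorafenib, 199 to 543 for the combination against control, 14 to 138 against givinostat and 0 to 36 against sorafenib. List shifts ranged from 37 to 47, the transfer correlations from 0.318 to 0.458 for givinostat and 0.433 to 0.574 for sorafenib, and the overlap of both drugs from 0 to 6. That overlap was 3 genes by the main design, 12 without background correction and in the series matrix, 5 with the background model on intensities alone, 6 with cyclic loess, and 0 with array median scaling or no detection filter. The transfer correlations moved to 0.23 and 0.319 with no detection filter.

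With an estimated correlation 8 of the 41 list shifts held: hypoxia and glycolysis and heat shock chaperones in sorafenib against control, the combination against control and the combination against givinostat, antigen presentation with sorafenib, and ER chaperones in the combination against givinostat. The other processing alternatives ended the G2/M shift with givinostat (array median scaling, strict detection), those of oxidative phosphorylation (cyclic loess) and ER chaperones (strict detection) with sorafenib, that of CDK inhibitors and p53 targets in the combination against control (no detection filter) and that of hypoxia in the interaction (both detection settings). Of the named genes that passed, 0 of 7, 9 of 45, 16 of 55, 2 of 35 and 0 of 20 passed in every alternative run for them, in the order above. No chip or array position is given, so a chip block was not run. Signal over background limits which genes could be tested, since 22.4% to 30.9% of probes were detected per array.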

Other observations

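The tests on histone genes and on control A below were chosen only after the results were seen; the test of the signal range on the A arrays was written before.

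Replication-dependent histone genes not matched by symbol to the fixed list, of which 19 were measured, were lower with sorafenib. In sorafenib against control 17 were negative with a median log2 change of -0.61 (limma's camera p = 2.11e-06, and p = 0.0254 with an estimated correlation). In the combination against givinostat, which shares no array with that comparison, 18 were negative with a median of -0.47 (camera p = 2.74e-05, and p = 0.0415 with an estimated correlation). In the combination against control 17 were negative with a median of -0.46 (camera p = 0.00121, and p = 0.0982 with an estimated correlation). H2AC8 and H3C7 were detected on none of the sorafenib arrays, and H2BC17, H2BC18 and H3C4 on 1 of the 3. On the combination arrays H3C3 was detected on none, and H2AC17, H2BC17 and H3C8 on 1 of the 3. The values of these genes rest partly on background signal. Over all genes H2AC8 fell in sorafenib against control, H3C3 and H2AC17 in the combination against givinostat and H3C3 in the combination against control, and these 3 had been seen before the tests. With givinostat alone 7 of the 19 were negative, with a median of 0.17 (limma's camera did not pass). Among the 19, H2AC25 stands on the fixed list under an older symbol, H2AW, that was not matched. Its log2 change was 0.06 in sorafenib against control and 0.42 in the combination against givinostat. A fall of replication-dependent histone transcripts with sorafenib may go with the lower level of DNA replication genes, a link that was not tested.

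IL22, chosen after its values were seen, had an interaction value of 1.5 ± 0.34 (limma adjusted p = 0.69), so its departure from the sum of both drugs did not pass. The level of MTAP, also chosen after its values were seen, was 8.93 on combination A, 10.42 on combination B and 10.36 on combination C on the log2 scale, against a mean of 7.63 with sorafenib; its probe was detected on none of the control arrays, so no interaction value is given.

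A smaller givinostat response on the arrays lettered A was examined as a hypothesis. The slope ratio of A over B and C was 0.823 (95% bootstrap interval 0.682 to 1.02), so the pattern itself does not exceed its spread between genes. The intervals for these ratios resample genes and not arrays, so the spread between arrays is not measured. A narrower signal range on the A arrays might produce it, and the sorafenib response gave a ratio of 0.876 (0.742 to 1.02). Control A out of place might as well, and the combination minus sorafenib gave 0.849 (0.741 to 1.03). That difference uses no control array, but its 50 genes and reference come from givinostat against control, so the check is not free of control A. Both intervals include the bound of 0.8, so these explanations cannot be told apart with 3 arrays per group.

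Other splits of the same 6 arrays into 3 and 3 gave 0 genes by limma in all 9 cases for each of the 5 pairwise comparisons, against 7, 273, 565, 136 and 29 for the real ones. So 1 of 10 splits was as large, and with 10 splits the share cannot go below 0.1. Each other split mixes arrays of both groups, so a drug effect adds to the spread within the drawn groups. The counts of these splits are therefore no measure of chance alone. For list shifts, 5 of 10 splits were as large for givinostat against control (real 5, highest other 9) and 6 of 10 for the combination against sorafenib (1 and 6). It was 1 of 10 for sorafenib against control (13 and 7), for the combination against control (11 and 7) and for the combination against givinostat (10 and 8), with the same limit. The splits with many lists follow the letter A. For givinostat against control the 4 other splits that keep both A arrays together gave 5 to 9 lists and the 5 that separate them 0 to 2; for the combination against sorafenib these were 4 to 6 and 0 to 1. Among the 4 splits that part all 3 letter pairs as the real one does, the others gave 0 to 2 lists for givinostat against control (real 5) and 1 to 4 for sorafenib against control (real 13). For the interaction the real count of genes is 0, so that 100 of 100 random draws of the 12 arrays reached it (highest other 492) was fixed beforehand and decides nothing. At least the real 1 list came from 82 of 100 draws (highest other 13), so chance is not excluded for it. Drug effects can remain in the drawn groups, and why some draws gave many genes was not tested.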
